A study of Astyanax mexicanus with 22 samples.

How the data were processed

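The series holds bulk RNA sequencing of Astyanax mexicanus ovaries. Per the labels' protocols, total RNA of the right-side ovary was extracted with Trizol, libraries were made with a strand-aware kit after depletion of ribosomal RNA, and they were sequenced on a Singular Genomics instrument. The submitters' processing notes name STAR 2.7.10b and RSEM without saying what each was used for. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are printed, and overlapping or antisense genes could not be told apart. A symbol on 2 gene rows is named as such. Such rows may be near copies that share reads, which was not tested. Gene symbols were taken from the deposited tables, which gave one for 16752 of 27420 genes.

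The authors deposited a table of whole-number counts per gene and library, and this table was used for all main tests. It also has 4 rows that name no gene, which were left out of library sizes and tests. Of all reads listed in a library (8470367 to 11727151), 55.4% to 67.6% were counted in genes, 7.91% to 17.6% were multimapping, 6.96% to 10.9% unmapped, 15.9% to 18.6% without a feature and 0.256% to 0.376% ambiguous. The authors also deposited a table of scaled CPM values for 14814 genes, treated here as a signal per gene. Its columns sum to 937145 to 1202370, so they are not plain CPM. Within each library they are a constant multiple of the counts, and they were used in 1 alternative.

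Libraries were grouped by morph (surface or Pachón), batch (old or new) and treatment (control or starved), as their titles give these. The samples, lists, tests and alternatives were fixed before the data were examined, except for what is named as chosen later here and in the closing section. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15607 genes, 12070 of them with a symbol. TMM factors (0.833 to 1.07) were computed, and a quasi-likelihood model with 8 group means was fitted to all 22 libraries with robust estimation, so that all groups share 1 estimate of the spread. The common dispersion was 0.0501 in this fit, 0.0742 in surface libraries alone and 0.0325 in Pachón libraries alone (biological coefficients of variation of 22.4%, 27.2% and 18%). Within groups, the median SD of log2 CPM lay between 0.13 (Pachón new starved) and 0.373 (surface new starved), and the correlation of log2 CPM between replicates between 0.935 and 0.98 over 23 pairs. The spread between replicates exceeded counting error, with a chi-square per degree of freedom of 3.72 to 36.4.

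The 12 comparisons were the starvation response in each morph and batch (4), its average over batches in each morph (2), the difference of the averaged response between morphs (Pachón minus surface), the difference of the response between batches in each morph (2), Pachón against surface fish in control and in starved fish (2), and old against new batch in controls. Averages weight the batches or morphs equally. Tests are 2-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was 0.05. The SE of a change is its size over the square root of the quasi-likelihood F. CPM values in the text are means ± SD over libraries of counts per 1e+06 gene counts scaled by TMM. Where a side had no count, the bound uses a floor of 3 counts per library, and with 1 to 3 counts the ratio of summed CPM is given with its 95% exact interval.

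The genes named were set by a rule: for each of the 6 averaged comparisons, the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean log2 CPM of at least 1 and the same sign in both batches (in both morphs for the batch comparison), and up to 4 members of each fixed list with the smallest p. The genes gdf9, bmp15, zar1, fshr, cyp19a1a and cyp17a1 and a few others could always be given. For Pachón starvation, where no gene was called, the named list members are those with the smallest p. Genes outside the rule are said to be so. A few genes that the rule selects are not reported here. The 41 gene lists covered cell types of the ovary and of neighbouring tissue, pathways of feeding and fasting, and cell machinery. Of these, 39 had at least 5 tested genes (998 genes in all). The lists of vitellogenins and of mitochondrially encoded genes were not tested. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. Fry asks whether the members move, on balance, in 1 direction. Read shares were compared with exact 2-sided permutation tests within batches, 8 in all, a comparison chosen after the shares had been seen. The batch comparison within each morph and its difference between morphs were read from the same fit.

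The pipeline was tested on simulated data for 15607 genes with 50 genes changed at each of 4 fold sizes. Each gene had its mean over all libraries and its spread in the fit of all 22 libraries, the same in both morphs. The larger spread of surface libraries (common dispersion 0.0742, against 0.0501 in the fit of all) was not simulated. Recovery and false calls in surface fish were therefore not tested at that spread. For the surface response edgeR recovered 40%, 50%, 84% and 96% of the genes changed 1.5-, 2-, 4- and 8-fold (138 called, 3 of them unchanged), and DESeq2 52%, 56%, 88% and 94% (159 called, 14 unchanged). For the Pachón response edgeR recovered 52%, 74%, 96% and 90%, for the control morph comparison 34%, 66%, 84% and 96%, and for the batch comparison 28%, 62%, 84% and 98%. Of 3 lists changed 1.5-fold camera called 3, and it called 0 others. The simulated genes were drawn independently of each other, so this could not test the preset correlation or the false list calls it may allow.

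The alternatives were RLE normalization, no filter on low counts, a replicate-number block, genes above 1% of a library's counts left out, DESeq2 1.42.0, voom with sample weights, a fit of only the groups compared, 1 effect shared across batches, limma-trend on the scaled CPM with a pseudocount of 1 or 0.1, and each library left out in turn. A fit that left a group with 1 library took its spread from the other groups. A crossed replicate block and an exact permutation of the list scores were added after seeing the data.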

Results

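Bulk RNA sequencing was carried out on right-side ovaries of Astyanax mexicanus, a freshwater fish with an eyed surface form and blind cave forms. Ovaries of surface fish and of fish from the Pachón cave were each taken from control and from starved animals. The samples came in batches labelled old and new. The series design mentions ages of about 500 and 1200 days after fertilization, without stating which batch had which age. The length of the starvation is not given in the sources used here. The 22 libraries fell into 8 groups. Surface fish gave 4 control and 2 starved libraries in the old batch and 2 control and 2 starved libraries in the new batch. Pachón fish gave 4 control and 4 starved libraries in the old batch and 2 control and 2 starved libraries in the new batch. Each library held between 4860620 and 7513790 counts in genes (median 5861974.5), and 15607 genes were abundant enough to be tested. Replicates are not stated to be separate fish, so each p-value measures the spread between these samples. Intervals on ratios of counts cover counting error only. Changes are log2 values of edgeR ± SE, and called means an adjusted p under 0.05.

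The libraries separated first by morph. The first principal component of log2 CPM (counts per 1e+06 gene counts) held 43.6% of the variance and placed the 10 surface libraries between -74.8 and -49.3 and the 12 Pachón libraries between 48.5 and 57.5. The second component, with 9.99%, separated the surface batches, with values of 8.15 to 43.7 in the old batch and -66.4 to -29.4 in the new batch. Pachón libraries of both batches lay between -8.19 and 12.1 on it. The third component, with 8.96%, placed replicate 2 of the starved surface fish of the new batch at -92, and the next lowest library was at -20.3. That library also had the lowest normalization factor (0.833) and the highest share of counts in 1 gene (1.06%).

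**Figure D1:**
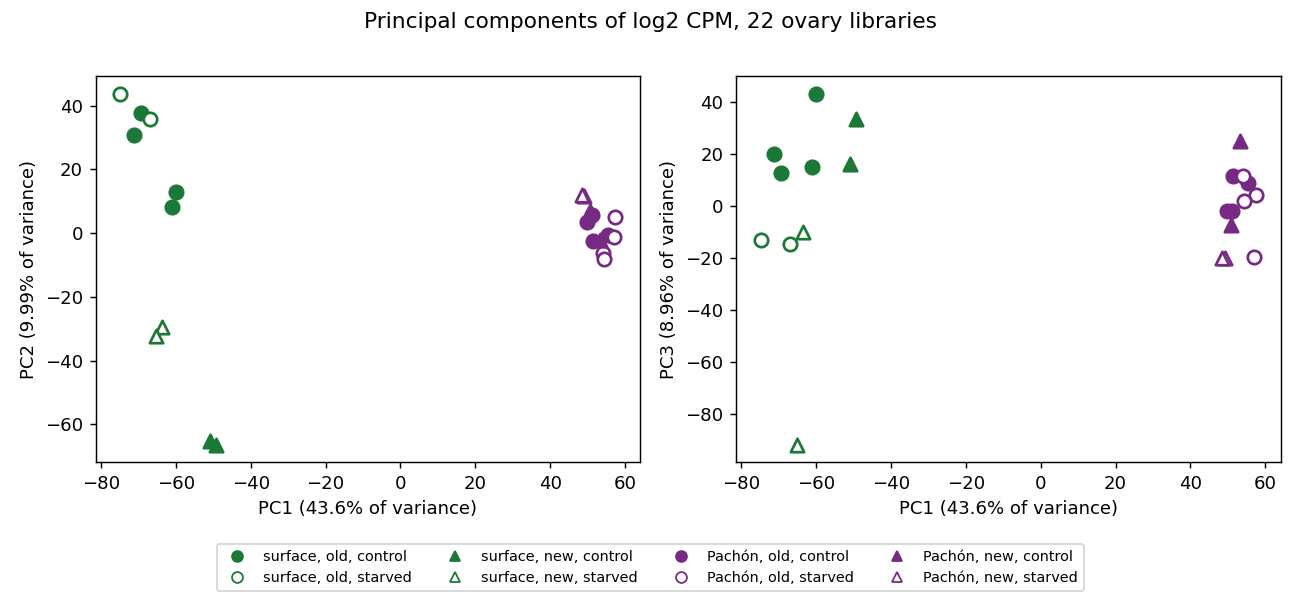
Principal components of log2 CPM for the 22 ovary libraries, with component 1 (43.6% of variance) on both horizontal axes and components 2 (9.99%) and 3 (8.96%) on the vertical axes. Each point is a library, green for surface fish and purple for Pachón, filled for control and open for starved, round for the old and triangular for the new batch. The morphs lie apart on component 1, and 1 starved surface library of the new batch lies at -92 on component 3.

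Starvation in surface fish was compared within each batch and averaged over both (6 control and 4 starved libraries). Genes of the ovarian somatic tissue were lower in starved fish. The smooth muscle actin gene acta2 (ENSAMXG00000007729) changed by -4.95 ± 0.70 (edgeR adjusted p = 0.000764), from 3.60 ± 2.97 to 0.367 ± 0.296 CPM (SD, n = 4 and 2) in the old batch and from 11.8 ± 1.39 to 0.0805 ± 0.114 CPM (SD, n = 2 and 2) in the new batch. COL6A1 (ENSAMXG00000008158), a collagen VI chain, changed by -3.31 ± 0.42 (edgeR adjusted p = 0.000488), and the luteinizing hormone receptor gene lhcgr (ENSAMXG00000034302) by -4.06 ± 0.72 (edgeR adjusted p = 0.00344). The aromatase gene cyp19a1a (ENSAMXG00000042616), whose product makes estrogen from androgen, changed by -3.02 ± 0.52, and cyp17a1, an enzyme gene of androgen synthesis, by -3.87 ± 0.69 (edgeR adjusted p = 0.00308 and 0.00333). The latter had 3 counts in starved libraries against 71 in controls, a ratio of 16.1 (counting interval 5.29 to 79.9). The values of cyp19a1a also rested on few reads, at 0.158 to 0.429 CPM in the starved libraries and 0.761 to 4.70 CPM in the controls. In total 378 genes were called higher and 838 lower in starved surface fish by edgeR, and 3975 of the 15607 genes had an unadjusted p under 0.05. Of the called genes, 555 changed 2-fold or more. These calls rest on a spread shared with the Pachón libraries: edgeR on the surface libraries alone called 0 genes (smallest adjusted p = 0.0552, 2919 genes with an unadjusted p under 0.05). The count also depended on the tool when all libraries were fitted. Voom with sample weights called 0 (smallest adjusted p = 0.0773, 2178 genes), DESeq2 1772 and limma on scaled CPM (pseudocount 1) 1292. The count also moved with single libraries, to 427 without replicate 2 and 4360 without replicate 1 of the starved new batch, 535 and 583 without replicates 1 and 2 of the starved old batch, and 750 and 472 without replicates 1 and 2 of the new-batch controls.

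The gene lists fixed for somatic cells of the ovary lay lower in starved surface fish. Of 18 measured genes of stroma and extracellular matrix, 10 fell and 0 rose (13 and 0 when adjusted over the list alone), with a median of -1.72. Among them were sparc, a secreted matrix protein gene (-2.82 ± 0.40, edgeR adjusted p = 0.000854), timp2a, a metalloproteinase inhibitor gene (-3.11 ± 0.58, edgeR adjusted p = 0.00461), and the collagen I chain gene col1a1b (-3.51 ± 0.67, edgeR adjusted p = 0.00491). Of 11 smooth muscle genes, 5 fell and 1 rose (7 and 1 adjusted over the list alone), with tagln at -2.91 ± 0.52 and the smooth muscle myosin gene myh11a at -1.89 ± 0.35 (edgeR adjusted p = 0.00328 and 0.00445). Of 12 granulosa cell genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone), among them foxl2b, a transcription factor gene of the ovary (-2.61 ± 0.51, edgeR adjusted p = 0.00508). Of 9 genes of steroid synthesis, 5 fell and 0 rose (6 and 1 adjusted over the list alone), with a median of -2.33. Camera, a test of a list against all other genes, called each of these lists with the preset correlation (adjusted p = 4.31e-10 for stroma, 0.000244 for smooth muscle, 3e-04 for granulosa cells and 0.000305 for steroid synthesis). With an estimated correlation none was called (adjusted p = 0.274, 0.0675, 0.274 and 0.274 in that order). Without replicate 1 of the starved new batch, camera no longer called granulosa cells (adjusted p = 0.106) or steroid synthesis (adjusted p = 0.083).

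The lists for other cell types were tested in the same way. Of 11 endothelial genes, 1 fell (1 adjusted over the list alone), with a median of -1.27 (camera adjusted p = 0.0271, and adjusted p = 0.466 with an estimated correlation). Of 20 macrophage genes, 2 fell (3 adjusted over the list alone), with a median of -0.85 (camera adjusted p = 0.0271, and adjusted p = 0.472 with an estimated correlation). One of these was cd74a, the invariant chain gene of antigen presentation, at -2.23 ± 0.41 (edgeR adjusted p = 0.00379). Camera did not keep the endothelial list without replicate 3 of the old controls (adjusted p = 0.0777), replicate 1 of the starved old batch (0.118) or replicate 1 of the starved new batch (0.134). The macrophage list was lost without replicate 4 of the old controls (0.0706), replicate 1 of the starved old batch (0.0513), replicate 1 of the new controls (0.0615) or replicate 1 of the starved new batch (0.219). Camera did not call the lists for erythrocytes (median -0.10), lymphocytes (-0.30), neutrophils (-0.17), adipocytes (-0.57), skeletal muscle (0.20), hepatocytes (0.09) or exocrine pancreas and gut (0.51). The share of multimapping reads was also lower in starved surface libraries, at 8.87% ± 1.31 (SD, n = 4) against 12.3% ± 1.63 (SD, n = 6) in controls (exact permutation p = 0.0111, adjusted p = 0.0222 over 8 tests).

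Among nutrient-related genes, 7 of 24 measured genes of the insulin, IGF and FOXO list fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 0.000416, and adjusted p = 0.301 with an estimated correlation). The IGF-binding protein gene igfbp2b changed by -2.22 ± 0.46, the transcription factor gene KLF15 by -2.70 ± 0.50 and the ubiquitin ligase gene fbxo32 by -0.56 ± 0.09 (edgeR adjusted p = 0.00818, 0.00437 and 0.00287). Of 34 fatty acid oxidation genes, 2 fell and 2 rose (3 and 2 adjusted over the list alone), a list that camera did not call. The carnitine palmitoyltransferase gene cpt1aa, which controls the entry of fatty acids into mitochondria, fell by 1.33 ± 0.21, and etfb, an electron transfer flavoprotein gene, rose by 0.49 ± 0.09 (edgeR adjusted p = 0.00186 and 0.00445). Fatty acid and triglyceride synthesis had 2 of 23 genes lower (6 adjusted over the list alone; median -0.26, camera adjusted p = 0.0421, and adjusted p = 0.329 with an estimated correlation). The replicate block ended that list's call (adjusted p = 0.054), and so did no filter on low counts (0.0864) and 6 of the 22 fits that left out 1 library. Of 45 autophagy genes 5 fell and 0 rose, of 34 genes of the ATF4 stress response 4 fell and 0 rose, and of 34 circadian clock genes 3 fell and 1 rose (6, 4 and 4 lower, and 0, 0 and 2 higher, adjusted over each list alone). Camera called none of these 3 lists (their medians were -0.06, -0.16 and -0.17).

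Lists of oocyte transcripts and of protein and energy machinery lay slightly higher in starved surface fish. The median change was 0.25 for 25 oocyte transcripts, 0.23 for 85 nuclear genes of oxidative phosphorylation, 0.24 for 79 ribosomal protein genes, 0.20 for 36 cell cycle genes, 0.16 for 74 mitochondrial ribosome genes and 0.16 for 40 proteasome genes. In these lists 2, 8, 2, 2, 4 and 4 genes rose and 0 fell (10, 12, 0, 9, 3 and 4 higher adjusted over each list alone). Camera called all 6 (adjusted p = 2.53e-05, 1.59e-09, 8.28e-09, 2.7e-06, 9.73e-06 and 9.73e-06). With an estimated correlation it called none of them (adjusted p = 0.466, 0.466, 0.497, 0.301, 0.274 and 0.466). Egg coat genes (9 genes, median 0.23) and DNA repair genes (48 genes, median 0.09) had 0 called members each (camera adjusted p = 0.0271 and 0.0421, and adjusted p = 0.497 and 0.274 with an estimated correlation). The oocyte growth factor gene bmp15 rose by 0.39 ± 0.09 (edgeR adjusted p = 0.016), a call lost without replicate 1 of the starved old batch (adjusted p = 0.0825) or replicate 2 of the new controls (0.085). The oocyte genes gdf9 (0.00 ± 0.08) and zar1 (0.64 ± 0.21) were not called (edgeR adjusted p = 0.992 and 0.0688). Without replicate 2 of the starved new batch the oocyte median was 0.07 and the ribosomal protein median 0.02, and camera called neither (adjusted p = 0.0792 and 0.495). The egg coat list was also lost without that library (0.413), without replicate 3 of the old controls (0.0561), replicate 1 of the starved old batch (0.0668) or replicate 2 of the new controls (0.082). DNA repair was lost in the replicate block (0.0841) and without replicate 3 (0.054) or 4 (0.0617) of the old controls, replicate 1 of the starved old batch (0.107), replicate 1 of the new controls (0.0615), or replicate 1 (0.196) or 2 (0.0541) of the starved new batch.

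The 8 largest falls in starved surface fish, besides acta2 and lhcgr, were in genes of transport, digestion and adhesion. The gene of the GABA transporter slc6a11a had 0 counts in the 4 starved libraries against 179 in the 6 controls, at least 10.1-fold lower with a floor of 3 counts per library. The taurine transporter gene slc6a6a had 2 counts against 187, a ratio of 63.6 (counting interval 17.4 to 529). The carboxypeptidase gene CPA1 had 3 counts against 151, a ratio of 34.2 (11.5 to 168). The aquaglyceroporin gene aqp9b changed by -5.69 ± 1.12 and the integrin gene ITGA4 by -5.36 ± 1.18 (edgeR adjusted p = 0.00602 and 0.0119). The anion exchanger gene slc26a4 was at least 5.04-fold lower. ITGA4 lost its call without replicate 1 or 2 of the starved old batch (adjusted p = 0.0567 and 0.0508). The call of slc26a4 was lost in the replicate block and without replicate 3 of the old controls (0.0706), replicate 1 (0.0591) or 2 (0.0536) of the starved old batch, replicate 2 of the new controls (0.0542) or replicate 2 of the starved new batch (0.061).

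The largest rises were led by lhx9, a homeobox gene of gonad formation, at 2.79 ± 0.54 (edgeR adjusted p = 0.00505), from 1.71 ± 2.05 to 8.33 ± 3.84 CPM (SD, n = 4 and 2) in the old and from 2.83 ± 0.789 to 28.1 ± 3.61 CPM (SD, n = 2 and 2) in the new batch. Its call held in each of the 22 fits that left out 1 library. The transcription factor gene dmrta2 rose by 2.20 ± 0.44, the cholesterol esterification gene soat2 by 2.57 ± 0.58, the fatty acid binding gene fabp1a by 2.39 ± 0.57 and SHISA6, a symbol on 2 gene rows, by 2.40 ± 0.59 (edgeR adjusted p = 0.00581, 0.0123, 0.0162 and 0.0199). Without replicate 2 of the starved new batch these 4 calls were lost (adjusted p = 0.08, 0.171, 0.195 and 0.122). Without replicate 2 of the new controls soat2, fabp1a and SHISA6 were not called (0.0556, 0.0676 and 0.0973), without replicate 2 of the starved old batch neither soat2 nor SHISA6 (0.118 and 0.0762), and without replicate 1 of the new controls not fabp1a (0.0733). ADAMTSL2, chrna4b and arxa had values of 2.75 ± 0.81, 2.62 ± 0.77 and 2.45 ± 0.74 (edgeR adjusted p = 0.0451, 0.0428 and 0.048), and lost their calls in 15, 12 and 17 of those 22 fits.

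**Figure D2:**
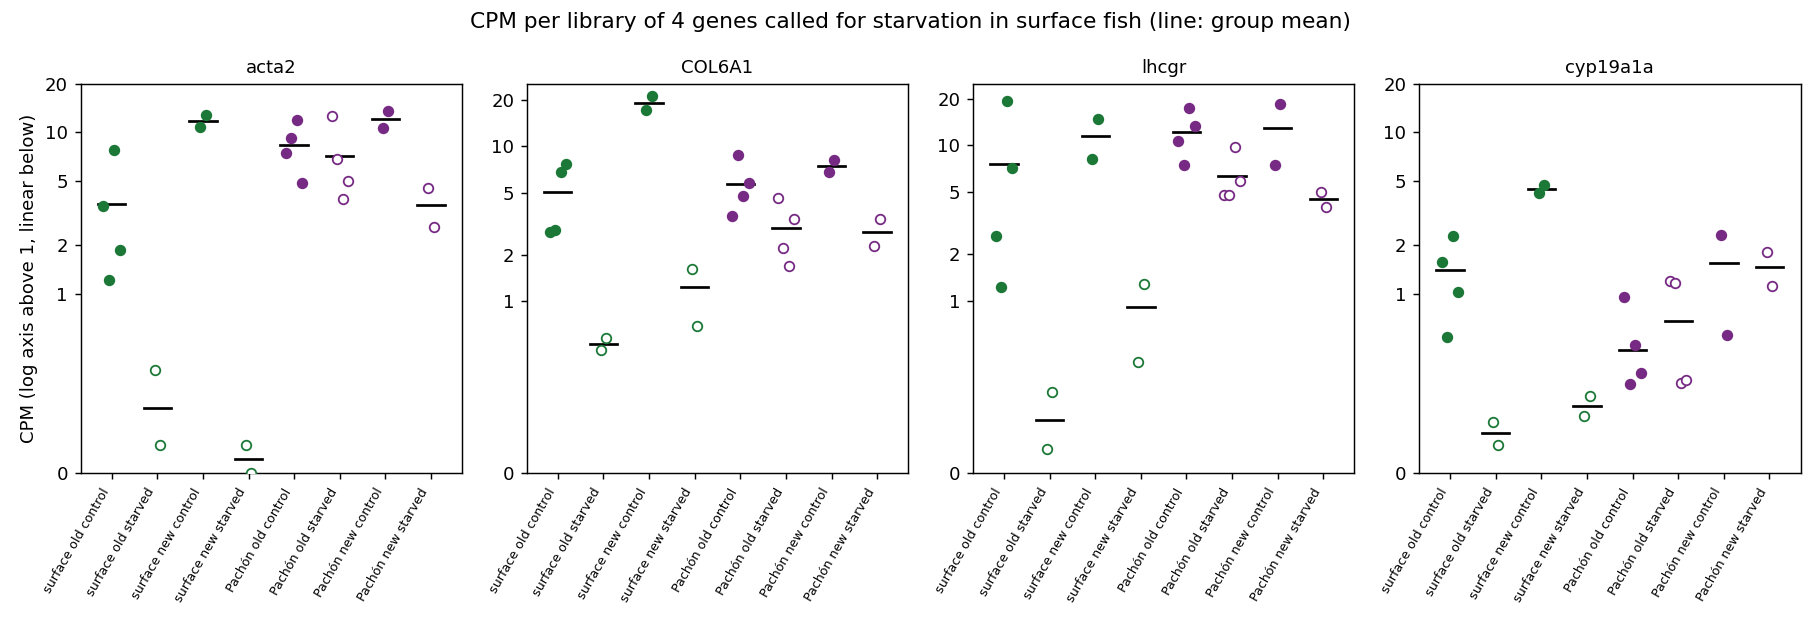
CPM per library of acta2, COL6A1, lhcgr and cyp19a1a on an axis that is logarithmic above 1 and linear below, for the 8 groups of surface fish (green) and Pachón fish (purple). Points are libraries, filled for control and open for starved, and lines are group means. The mean of acta2 in the new batch is 11.8 CPM in surface controls and 0.0805 in starved surface fish, and in Pachón 12.1 and 3.55. In the old batch these means are 3.60 and 0.367, and in Pachón 8.36 and 7.10.

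Taken batch by batch, the surface response gave 4 genes higher and 19 lower in the old batch (4 control against 2 starved libraries, 2119 genes with an unadjusted p under 0.05) and 241 higher and 411 lower in the new batch (2 against 2, 3422 genes). Several somatic genes had changes in the same direction in both batches. For acta2 these were -3.18 in the old and -6.73 in the new batch (edgeR adjusted p = 0.107 and 0.00312), for COL6A1 -2.71 and -3.90 (0.0626 and 0.00251), for sparc -2.72 and -2.92 (0.0619 and 0.00786) and for cyp19a1a -2.53 and -3.52 (0.136 and 0.0129). For lhcgr they were -4.54 and -3.58 (0.0797 and 0.0464), and for cyp17a1 -4.41 and -3.34 (0.0629 and 0.055). The batches shared 5 genes called lower, against 0.5 from independent lists, and 0 called higher, and across all genes the changes correlated with Pearson's r = 0.282 and Spearman's rho = 0.299 (genes are not independent replicates). The difference of the response between batches was called for 29 genes that were higher and 26 that were lower in old minus new (1549 with an unadjusted p under 0.05). Other tools and single libraries moved these counts. For the old batch DESeq2 called 301 genes, voom with sample weights 78, the replicate block 3 and edgeR on these groups alone 0 (2445 genes with an unadjusted p under 0.05). For the new batch DESeq2 called 1116, voom with sample weights 3, the replicate block 311 and edgeR on these groups alone 0 (1390 genes). The old-batch count was 118 and 14 without surface old controls 2 and 3, 13 without each of Pachón old controls 1 to 4, 15 without surface old starved 2, 366 and 375 without surface new starved 1 and 2, and 15 without Pachón new starved 2. The new-batch count was 3661 and 196 without surface new starved 1 and 2, and 230 and 200 without surface new controls 1 and 2.

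In Pachón fish no gene was called for starvation over both batches (6 control and 6 starved libraries). Among the somatic genes named above, COL6A1 had a change of -1.17 ± 0.34, timp2a of -1.35 ± 0.43, lhcgr of -1.23 ± 0.50, cyp17a1 of -1.19 ± 0.44 and acta2 of -0.998 ± 0.41 (edgeR adjusted p = 0.587, 0.617, 0.635, 0.635 and 0.635). The insulin-like growth factor receptor gene igf1ra had -0.59 ± 0.17 and the insulin receptor substrate gene irs2a -0.82 ± 0.26 (edgeR adjusted p = 0.587 and 0.617). For cyp19a1a the value was 0.11 ± 0.41 (edgeR adjusted p = 0.966), for fshr, the follicle-stimulating hormone receptor gene, -0.79 ± 0.54 (0.753), for the estrogen receptor gene esr2a -1.35 ± 0.57 (0.653), and for the oocyte genes gdf9, bmp15 and zar1 0.01 ± 0.08, 0.06 ± 0.08 and 0.18 ± 0.20. EdgeR called 0 genes, with 1142 of 15607 at an unadjusted p under 0.05 and a smallest adjusted p of 0.326. DESeq2 called 12, limma on scaled CPM 1, voom with sample weights 0 (1693 genes at an unadjusted p under 0.05) and edgeR on the Pachón libraries alone 0 (1715 genes). The count was 3 without Pachón old control 3 and 1 without Pachón new starved 2. In the new batch edgeR called 0 genes (876 at an unadjusted p under 0.05), DESeq2 5, and edgeR on these groups alone 2. In the old batch it called 1 (676 at an unadjusted p under 0.05), DESeq2 5, and edgeR on these groups alone 2. That gene was AP3B1, a vesicle adaptor subunit gene, at -0.99 (edgeR adjusted p = 0.000488), which lies outside the rule for named genes and was chosen after its values were seen. No gene was called for a different response between the Pachón batches (edgeR 0, with 481 at an unadjusted p under 0.05, DESeq2 1 and voom with sample weights 1).

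Camera called 12 lists in Pachón with the preset correlation (7 higher and 5 lower), and 0 with an estimated correlation (smallest adjusted p = 0.469). The 5 lower lists and some of the 7 higher ones are described here. Of 24 insulin, IGF and FOXO genes 22 had negative values (median -0.28, camera adjusted p = 0.000303, and adjusted p = 0.476 with an estimated correlation). Steroid synthesis had a median of -0.79, granulosa cells of -0.62, stroma of -0.36 and smooth muscle of -0.35 (camera adjusted p = 0.0053, 0.0053, 0.00695 and 0.00989, and adjusted p = 0.476, 0.476, 0.612 and 0.469 with an estimated correlation). On the other side, 79 ribosomal protein genes had a median of 0.18, 85 oxidative phosphorylation genes 0.10, egg coat genes 0.22 and oocyte transcripts 0.13 (camera adjusted p = 9.2e-13, 0.000303, 0.0011 and 0.0053, and adjusted p = 0.612, 0.673, 0.504 and 0.673 with an estimated correlation). With the preset correlation camera called 2 lists in the old and 12 in the new batch, and 12 for the difference between the batches. For that difference 0 lists were called by camera with an estimated correlation (smallest adjusted p = 0.648) and 0 by fry (smallest adjusted p = 0.71). The medians in the old and new batch were -0.01 and 0.34 for ribosomal proteins, -0.03 and 0.20 for oxidative phosphorylation, -0.02 and -0.74 for stroma and -0.05 and -1.02 for smooth muscle. The difference between batches had camera adjusted p = 7.4e-19, 1.55e-09, 0.0174 and 0.0318 (adjusted p = 0.648, 0.648, 0.707 and 0.648 with an estimated correlation). The hepatocyte list, markers of another tissue, had the largest median difference of the 12 (2.05, camera adjusted p = 0.0204, and adjusted p = 0.648 with an estimated correlation), with 1.34 in the old and -0.21 in the new batch. The other 7 were oocyte transcripts (-0.27), egg coat (-0.37), cell cycle (-0.11), mitochondrial ribosome (-0.12), proteasome (-0.12), insulin, IGF and FOXO genes (0.30) and clock genes (0.21). Across genes the changes in the Pachón batches correlated with Pearson's r = 0.0673 and Spearman's rho = 0.163. The ribosomal protein gene rps24 had 0.37 ± 0.13 (edgeR adjusted p = 0.634). No member of any of the 12 lists was called over all genes, and 1 stroma gene was lower when adjusted over the list alone. Without Pachón new control 2 camera did not call stroma (adjusted p = 0.0965), insulin, IGF and FOXO genes (0.101), oxidative phosphorylation (0.333), egg coat (0.237) or oocyte transcripts (0.546). Oocyte transcripts were also lost without Pachón old starved 3 (0.0829), granulosa cells without Pachón new starved 2 (0.0528), and stroma with no filter on low counts (0.0769). As in surface fish, the share of multimapping reads was lower in starved libraries, at 9.64% ± 1.17 against 13.8% ± 2.66 (SD, n = 6 each, exact permutation p = 0.00952, adjusted p = 0.0222 over 8 tests).

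Whether the morphs responded differently was tested as the Pachón response minus the surface response. EdgeR called 4 genes, each with a higher value in the Pachón response. TINAGL1 (ENSAMXG00000014689), a basement membrane protein gene, differed by 2.08 ± 0.26 (edgeR adjusted p = 0.00331), with changes of -1.94 in surface fish and 0.14 in Pachón. Its level was 27.8 ± 1.72 CPM in control and 2.33 ± 0.569 CPM in starved surface fish of the new batch (SD, n = 2 and 2) and was 2.78 ± 0.503 and 2.23 ± 1.53 CPM in the old batch (SD, n = 4 and 2). Its difference was 0.68 in the old and 3.48 in the new batch. The integrin gene itga3b differed by 2.63 ± 0.42 and the thrombospondin gene thbs3b by 1.44 ± 0.22 (edgeR adjusted p = 0.0201 and 0.0122), with 3.22 and 0.28 in the old and 2.05 and 2.60 in the new batch. The gene ENSAMXG00000001295, without a symbol in the files and therefore outside the rule for named genes, differed by 3.72 (edgeR adjusted p = 0.00949) and was named after its values were seen. Differences for acta2 (3.95 ± 0.84), cyp19a1a (3.13 ± 0.66), sparc (2.33 ± 0.51) and cyp17a1 (2.68 ± 0.83) were not called (edgeR adjusted p = 0.0876, 0.0876, 0.0997 and 0.271). Unadjusted p-values under 0.05 were found for 1446 genes, DESeq2 called 107, voom with sample weights 0 (824 genes at an unadjusted p under 0.05) and a fit with 1 effect shared by both batches 1. Without single libraries the count was 22 (surface old control 2), 15 (surface old starved 2), 13 (surface new control 1), 1 (Pachón new control 1), 818 (surface new starved 1) and 2 (Pachón new starved 1). Of the named genes, itga3b was lost without surface old starved 1 (adjusted p = 0.0805), surface new control 2 (0.0617), Pachón new control 1 (0.0831) or Pachón new starved 1 (0.079), thbs3b without the last 2 (0.0588 and 0.055) and in the replicate block, and ENSAMXG00000001295 without Pachón new control 1 (0.0588). Without surface new starved 1, acta2, sparc and cyp19a1a were called (0.024, 0.0232 and 0.0276), and acta2 also without surface old control 2 (0.041).

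By list, camera placed the Pachón response above the surface response for stroma (median difference 1.38), steroid synthesis (1.38), smooth muscle (1.12), macrophages (1.02), granulosa cells (0.86) and fatty acid and triglyceride synthesis (0.25). It placed it below for oocyte transcripts (-0.18), cell cycle (-0.15), oxidative phosphorylation (-0.13), the proteasome (-0.12) and the mitochondrial ribosome (-0.09). The preset correlation gave adjusted p-values from 1.99e-08 for stroma to 0.0233 for granulosa cells. With an estimated correlation 0 of these 11 lists were called (smallest adjusted p = 0.239, for smooth muscle). Adjusted over each list alone, 4 stroma genes, 2 steroid synthesis genes, 3 smooth muscle genes and 1 granulosa cell gene were higher and 1 smooth muscle gene was lower, and 0 members were called over all genes. Without surface new starved 1 camera did not call granulosa cells (adjusted p = 0.371), steroid synthesis (0.217), smooth muscle (0.0974) or macrophages (0.0641). Granulosa cells were also lost with no filter on low counts (0.0512) and without surface old control 3 (0.0672), surface old starved 1 (0.0891), surface new control 2 (0.104), Pachón new control 1 (0.068) or Pachón new starved 1 (0.118), and steroid synthesis without surface old starved 1 (0.14). Fatty acid and triglyceride synthesis was lost without surface old starved 2 (0.0825), surface new control 2 (0.0705) or surface new starved 2 (0.0689). Without surface new starved 2 it did not call the cell cycle (0.127), oxidative phosphorylation (0.675), the proteasome (0.271), the mitochondrial ribosome (0.271) or oocyte transcripts (0.83), whose median was then 0.03. Oocyte transcripts and the mitochondrial ribosome were also lost without surface new control 2 (0.104 and 0.0876) or Pachón new control 1 (0.327 and 0.0861). Across genes, the surface and Pachón changes correlated with Pearson's r = 0.254 and Spearman's rho = 0.36, in comparisons that share no library. Of the genes called in surface fish, 87.8% of those higher and 84.5% of those lower had the same sign in Pachón, with Pachón medians of 0.147 and -0.234 against 0.455 and -1.16 in surface fish. In log2 CPM the Pachón medians lay 0.364 apart, and 24 of 420 splits of the Pachón labels gave as large a difference (exact permutation p = 0.0571, at most 0.434 in another split), so the shared direction did not pass this test.

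**Figure D3:**
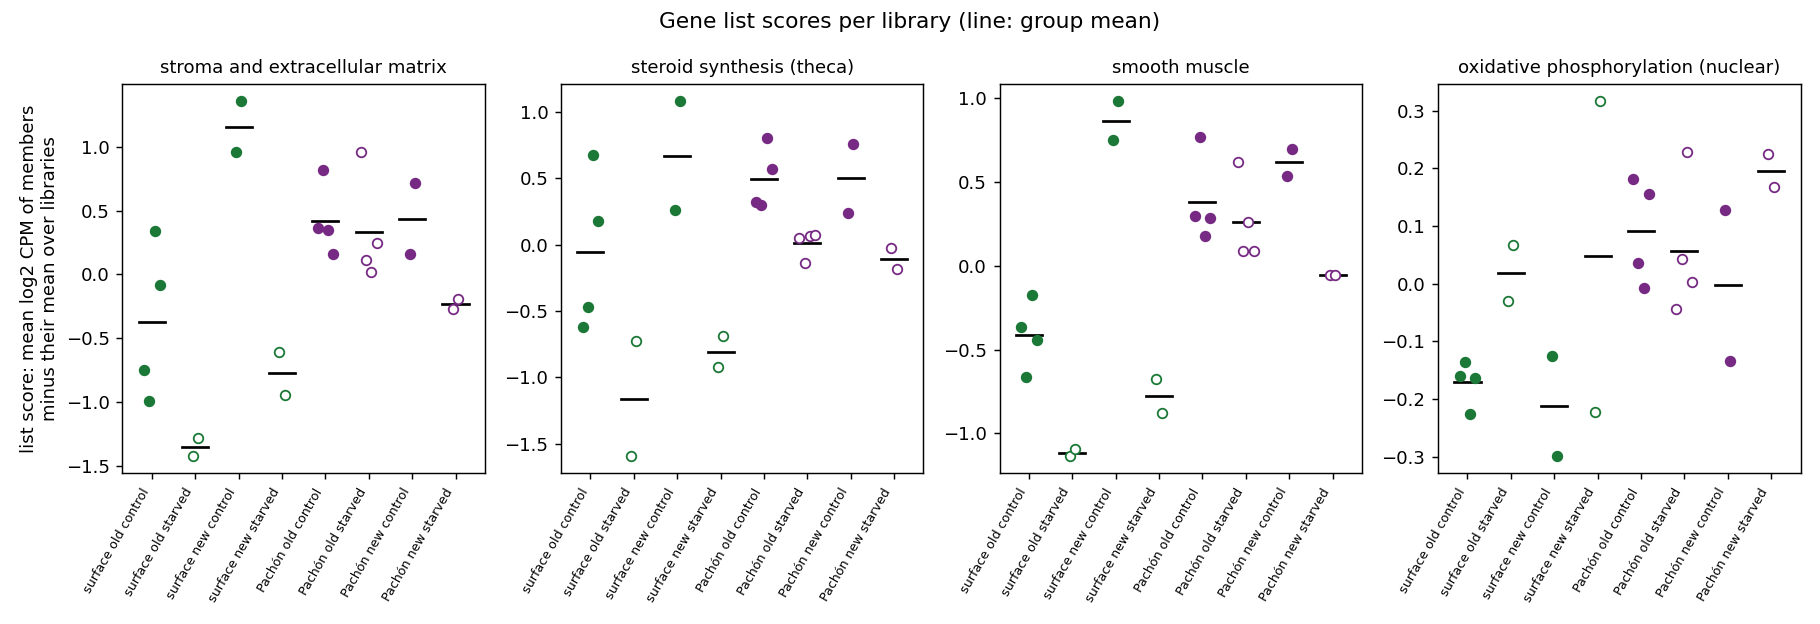
Scores of 4 gene lists (mean log2 CPM of the members minus their mean over libraries) in the 8 groups, green for surface fish and purple for Pachón, filled for control and open for starved, with lines at group means. In surface fish the stroma score was 0.956 and 1.36 in new controls and -0.606 and -0.945 in new starved libraries. Steroid synthesis scores in Pachón lay between 0.239 and 0.802 in controls and between -0.186 and 0.07 in starved libraries.

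Pachón ovaries differed from surface ovaries in a large part of the transcriptome. In control fish (6 against 6 libraries) edgeR called 2585 genes higher and 2816 lower in Pachón, 2411 of them by 2-fold or more, with 6895 at an unadjusted p under 0.05. The insulin receptor substrate gene irs2a (ENSAMXG00000025890) was lower in Pachón by -3.23 ± 0.23 (edgeR adjusted p = 5.27e-09), at 47.9 ± 3.74 CPM in surface and 6.71 ± 0.909 CPM in Pachón controls of the old batch (SD, n = 4 and 4) and 48.9 ± 1.88 and 3.96 ± 2.05 CPM in the new batch (SD, n = 2 and 2). Among the 8 largest rises, the innate DNA-sensing gene sting1 had 1 count in surface controls against 506 in Pachón controls, a ratio of 547 (counting interval 97.8 to 21700). LIN7B, a cell polarity gene, had 3 against 921 counts (332, 113 to 1610), and TMEM65 1 against 159 (172, 30.4 to 6830). ADCYAP1R1, the receptor gene of the neuropeptide PACAP, had 3 against 178 counts (64.2, 21.6 to 314). Without a count in surface controls were the cone channel gene CNGA3 (at least 44-fold higher in Pachón; a symbol on 2 gene rows), adamts10 (at least 9.14-fold) and CPA6 (at least 11-fold). The antigen receptor recombination gene rag1 had 1 against 413 counts (447, 79.7 to 17700) and was not called without Pachón new control 2 or with sample weights.

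Among the 8 largest falls in control fish, ubtd1a had no count in Pachón (at least 27.1-fold lower). The phosphatase-family gene plpp7a had 1 count in Pachón against 457 in surface fish (423, 75.5 to 16700), and LRRC73 1 against 297 (275, 48.9 to 10900). The value of lrit3a was -8.07 ± 0.53 (edgeR adjusted p = 2.22e-09), with 6 against 1548 counts. The lactase gene LCT and or70a15, an odorant receptor gene by its name, had no count in Pachón (at least 45.4-fold and 14.8-fold lower), and the fetuin gene ahsg2 had 1 against 754 (697, 125 to 27600). Without surface old control 4, ahsg2 and or70a15 were not called (adjusted p = 1 for both). The call of or70a15 was also lost without surface new control 1 (0.0747) or 2 (0.0514) and Pachón new control 1 (0.102) or 2 (0.095). LCT was lost without surface new control 1 (0.0748), Pachón new control 1 (0.0677) or 2 (0.0628), with sample weights, with no filter and in the compared groups alone.

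Members of the fixed lists were called in both directions between control morphs, where 5401 of all 15607 genes were called. Of 85 oxidative phosphorylation genes, 30 were higher and 4 lower in Pachón (32 and 4 adjusted over the list alone), with ndufs5 at 1.00 ± 0.16, uqcrh at 0.61 ± 0.11 and ndufs8a at -1.25 ± 0.18 (edgeR adjusted p = 7.21e-05, 0.000226 and 3.28e-05). Of 79 ribosomal protein genes, 12 were higher and 0 lower (4 and 0 adjusted over the list alone), with rpl22 at 0.79 ± 0.17 (edgeR adjusted p = 0.00158). Of 23 genes of fatty acid and triglyceride synthesis, 3 were higher and 11 lower (3 and 11 adjusted over the list alone), with mid1ip1a at -1.93 ± 0.20 and the elongase gene elovl5 at -1.27 ± 0.14 against the triglyceride synthesis gene dgat1b at 0.71 ± 0.10 (edgeR adjusted p = 6.93e-07, 1.49e-06 and 3.19e-05). Camera called these 3 lists (adjusted p = 0.0194, 0.0441 and 0.0441; adjusted p = 0.977 for each with an estimated correlation). The oxidative phosphorylation call was lost without Pachón old control 1 (adjusted p = 0.0579), surface new control 2 (0.164) or Pachón new control 1 (0.425), and the ribosomal and fatty acid calls in 9 and 10 of the 22 fits without 1 library and in the replicate block (0.0683 and 0.0669). Of 25 genes of cholesterol synthesis and uptake, 2 were higher and 10 lower, among the latter the lanosterol synthase gene lss (-2.15 ± 0.29, edgeR adjusted p = 1.67e-05). Of 34 clock genes, 8 were higher and 8 lower, with nfil3-5 at 1.73 ± 0.12 and bmal1a, a core activator of the clock, at -1.26 ± 0.13 (edgeR adjusted p = 5.23e-09 and 6.9e-07), and hlfb with 178 counts against 3 (ratio 64.2, counting interval 21.6 to 314). Of 15 meiosis genes, 4 were higher and 4 lower, with the synaptonemal complex gene sycp1 at 2.44 ± 0.29 (edgeR adjusted p = 3.76e-06). Adjusted over each list alone, 3, 8 and 5 of these genes were higher and 10, 8 and 5 lower, and camera called none of the 3 lists. The leukocyte actin-binding gene coro1a was higher in Pachón by 3.23 ± 0.25 (edgeR adjusted p = 1.34e-08), and cyp19a1a was lower by -1.26 ± 0.40 (0.0199), a call lost without surface new control 2 (0.0556) or Pachón new control 2 (0.104).

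In starved fish (4 surface and 6 Pachón libraries) edgeR called 2853 genes higher and 2764 lower in Pachón, 2693 of them by 2-fold or more, with 7016 at an unadjusted p under 0.05. Somatic genes named for the surface response were also compared here. This comparison uses the same 4 starved surface libraries in which they were low, so a higher value in Pachón follows in part from their choice, and the difference of the responses was not called for acta2, cyp17a1, lhcgr or cyp19a1a. The value was 4.58 ± 0.70 for acta2, 3.35 ± 0.70 for cyp17a1, 3.26 ± 0.73 for lhcgr and 1.88 ± 0.53 for cyp19a1a (edgeR adjusted p = 6.46e-05, 0.00113, 0.00203 and 0.00986). For cyp17a1 this was 58 counts against 3, a ratio of 11.7 (counting interval 3.8 to 58.3). Of 18 stroma genes, 11 were higher and 1 lower in Pachón (12 and 1 adjusted over the list alone), with a median of 1.30, among them sparc (1.98 ± 0.40, edgeR adjusted p = 0.000884) and the collagen I chain gene col1a2 (3.32 ± 0.65, edgeR adjusted p = 0.000692). Camera called this list with the preset correlation (adjusted p = 0.0477; adjusted p = 0.914 with an estimated correlation), but not with RLE normalization (0.0549), in the replicate block (0.0505) or in 13 of the 22 fits without 1 library. Of 11 smooth muscle genes 7 were higher and 1 lower, of 9 steroid synthesis genes 5 and 0, of 12 granulosa cell genes 5 and 1, and of 20 macrophage genes 7 and 1, and camera called none of these lists. The glucocorticoid-responsive transcription factor gene KLF15 was higher in Pachón by 3.81 ± 0.48, the pyruvate dehydrogenase kinase gene pdk4 by 2.73 ± 0.50 and the clock gene per3 by 2.03 ± 0.22, and irs2a was lower by -4.08 ± 0.25 (edgeR adjusted p = 8.34e-06, 0.000339, 1.48e-06 and 9.83e-10). With sample weights 3489 genes were called in place of 5617, and the calls of acta2, cyp17a1, lhcgr, cyp19a1a and col1a2 were lost.

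The largest morph differences in starved fish included several of those in controls. CNGA3 had 2 counts in starved surface fish against 821 in starved Pachón (ratio 248, counting interval 68.4 to 2050), ADCYAP1R1 had none (at least 11.5-fold higher in Pachón), plpp7a had 2 counts in Pachón against 390 in surface fish (323, 88.8 to 2670), ubtd1a 2 against 286 (237, 64.9 to 1960), and lrit3a was at -7.58 ± 0.50 (edgeR adjusted p = 2.38e-09). Others entered the 8 largest in starved fish alone, a matter of rank, and may differ in controls too. For ucp1 the highest value in surface old controls was 0.152 CPM. The growth factor receptor gene erbb3b had 2 counts in surface fish against 1320 (399, 110 to 3300), cfap45 3 against 574 (116, 39.4 to 562), and the thermogenic uncoupling protein gene ucp1 2 against 370 (112, 30.7 to 926). The values of ddx18 and slc26a4 were at least 22.6-fold and 8.87-fold higher, with ddx18 on 2 gene rows, and MEGF6, also on 2 rows, was at 7.19 ± 0.52 (edgeR adjusted p = 1.53e-08). The gene slc26a4 was also among the largest falls in the same starved surface libraries. Lower in Pachón were RBPJL (-7.09 ± 0.65), KATNBL1 (-7.14 ± 0.98) and the lipoxygenase gene alox12 (-9.60 ± 1.57, edgeR adjusted p = 3.07e-07, 2.57e-05 and 0.000247), the last not called with sample weights. LCT had 2 against 1522 counts (1260, 348 to 10400) and ptprja 2 against 218 (180, 49.4 to 1500). These calls were lost with sample weights, LCT also without surface new starved 1 (adjusted p = 0.0684) and ptprja without surface new starved 2 (adjusted p = 1). Control and starved fish shared 1768 genes called higher and 1938 called lower in Pachón, against 473 and 499 from independent lists, in comparisons that share no library (Pearson's r = 0.837, Spearman's rho = 0.766 across genes, which are not independent replicates).

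Old and new batches were compared in controls (8 against 4 libraries), as old minus new and averaged over the morphs. Batch and age cannot be told apart in this comparison. The sulfide-oxidizing enzyme gene sqor (ENSAMXG00000000587) was lower in the old batch by -2.66 ± 0.27 (edgeR adjusted p = 4.4e-05), at 6.02 ± 2.23 against 221 ± 160 CPM in surface fish (SD, n = 4 and 2) and 27.5 ± 1.89 against 30.3 ± 2.44 CPM in Pachón (SD, n = 4 and 2). The hypoxia-inducible factor gene hif1aa was lower by -3.62 ± 0.51 on average (edgeR adjusted p = 0.00137), a call lost in the replicate block, with -4.63 in surface fish alone (0.000776) and -2.60 in Pachón alone, which was not called (0.588). The adaptor gene GAB2 was higher in the old batch by 2.03 ± 0.28 (edgeR adjusted p = 0.001), with 3.70 in surface fish and 0.36 in Pachón. In all, edgeR called 79 genes higher and 115 lower in the old batch (2187 at an unadjusted p under 0.05), DESeq2 486, voom with sample weights 489, edgeR on the controls alone 298 and the replicate block 20. The count was 60 and 89 without Pachón new controls 2 and 1, 94 and 125 without surface new controls 1 and 2, 127 and 112 without Pachón old controls 1 and 4, and 408 and 409 without surface new starved 1 and 2. Within a morph, 468 genes were higher and 680 lower in the old batch of surface controls, against 4 and 1 in Pachón, and the batch effect differed between morphs for 159 genes by its own test. The 5 Pachón genes, named after their values were seen, were atl3, CARF, ENSAMXG00000042898 and slc25a11 with higher and pycard with lower values in the old batch.

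Averaged over the morphs, smooth muscle genes (median -1.11) and stroma genes (median -0.86) lay lower in the controls of the old batch (camera adjusted p = 8.68e-05 and 1.97e-06). In this average smooth muscle was also called with an estimated correlation (adjusted p = 0.0232) and stroma was not (adjusted p = 0.653). The medians were -1.73 and -1.74 in surface fish alone (camera adjusted p = 0.000481 and 1.89e-08, and adjusted p = 0.0549 and 0.338 with an estimated correlation), and -0.11 and 0.00 in Pachón alone (camera adjusted p = 0.485 and 0.958). The difference between morphs was called for both by camera (adjusted p = 0.0155 and 1.24e-06), and not with an estimated correlation (adjusted p = 0.385 for each). Camera called 7 lists lower in surface fish alone, and in Pachón alone 0 lower and 2 higher, and with an estimated correlation it called 0 in either morph alone. In the average over morphs no member of the smooth muscle and stroma lists was called over all genes, and 6 smooth muscle and 9 stroma genes were lower when adjusted over the list alone. The values of the intermediate filament gene desma (-1.29) and the collagen VI chain gene COL6A2 (-1.36) had edgeR adjusted p = 0.0525 and 0.0695. Granulosa cells (median -0.55), endothelium (-0.39), the ATF4 stress response (-0.16), oxidative phosphorylation (0.09) and the mitochondrial ribosome (0.04) were also called by camera in this average. Their adjusted p-values were 0.0146, 0.0239, 0.0146, 0.0146 and 0.0362, and adjusted p = 0.653, 0.653, 0.653, 0.883 and 0.734 with an estimated correlation. Each of these 5 calls was lost without at least 1 library, granulosa cells without surface new control 2 (adjusted p = 0.16) or Pachón new control 2 (0.0664). Among other large changes, b3gnt5a was at 3.93 ± 0.70 and adm2a, an adrenomedullin-family gene, at -4.24 ± 0.76 (edgeR adjusted p = 0.00982 and 0.00935). The call of b3gnt5a was lost without Pachón new control 1 (0.0598) or 2 (0.0683), that of adm2a without surface new control 1 (0.144) or Pachón new control 2 (0.0511), and both in the replicate block. The other named genes, ARHGAP44, TRIM50, CNNM1, asic1c, pald1a and nr2e3 (higher) and optc, OSBPL3, COL14A1 and cmah (lower), each lost the call in the replicate block and without at least 1 library.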

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

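The tests of read shares, of a single library, of read composition, of strain variants and of a batch shared by both morphs were chosen only after the results they bear on were seen, while the test of somatic cells and the counts over other splits of the samples were set before.

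The genes called for starvation in surface fish are the first pattern a reader may want to follow up, and chance can be excluded for their number, since 1 of the 90 splits of the labels within batches, the real one, gave as many genes (1216, and at most 825 in the others, by a split that exchanged control and starved labels in the new batch). Read composition, a lower share of multimapping reads in starved libraries, stays open. That share fell at least as much in Pachón. The Pachón difference between the genes higher and lower in surface fish was 23% of the surface one (0.364, exact permutation p = 0.0571). It was at most 0.434 on the log2 scale in any other of 420 splits, against medians of 0.445 and -1.13 in surface fish. These genes were chosen by their change in the same surface libraries, which enlarges the surface difference. A smaller difference in Pachón could therefore be found for a shared cause too, so this test cannot decide. The library far from the others, replicate 2 of the starved new batch, is argued against as the sole source. Without it 1 of 45 splits, the real one, gave as many genes as the real labels. A test run earlier for the same question used the stroma list in the old batch, which lacks that library. The medians were -1.06 in the old and -2.34 in the new batch. The 2-sided exact permutation p over 15 splits was 0.133, and the smallest possible was 0.0667. A lower share of somatic cells in the starved surface ovaries stays a candidate explanation: of 776 genes called lower that are in none of the fixed lists, 82.1% rose with a somatic score of 61 genes among Pachón libraries of one group, more than in 95% of 2304 permutations (exact permutation p = 0.0195, 54.1% over all genes), and the medians of stroma, smooth muscle, granulosa cells and steroid synthesis were all lower. Of 341 genes called higher, 78.3% fell with that score, a share that did not pass the same test (exact permutation p = 0.0707), so the explanation stays open for them. Whether the tissue changed or the dissected part differed is open, and so is a change of expression within cells.

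The genes without a count in 1 morph are the second pattern. A strain variant against the reference would be expected to remove reads mainly in 1 morph. It is argued against only as the cause of all 24 such genes together. Of these, 13 had no count in Pachón and 11 none in surface fish, 45.8% for the morph with fewer (exact 95% interval 25.6% to 67.2%). All genes without a count in either 1 of the morphs may still owe their 0 to such variants, which these numbers cannot exclude. Genes with a few counts in the lower morph, such as sting1 and plpp7a, are not among these 24. Strain variants were not tested for them or for the other genes called between the morphs. The build is not given in the sources used here. Differences of 8-fold or more were 333 higher and 295 lower in Pachón controls and 513 higher and 254 lower in starved Pachón fish. A biological difference of the morphs stays open and was not tested apart.

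The difference between batches in surface controls is the third pattern. A sequencing or library batch shared by both morphs is argued against for these genes: of 1148 genes called in surface fish, 51.6% changed the same way between the Pachón batches, about what chance gives, with a median size of 0.188 there against 1.53 in surface fish. A batch step done on surface fish alone, and the age of the fish, may each account for it, and neither can be told apart from the batch. Stroma and smooth muscle lists also lay lower in the old surface controls by camera with the preset correlation. A different share of somatic cells or a different dissected part therefore stays open here too, and was not tested. The same surface controls also enter the starvation comparison of the first pattern.

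For the other comparisons the counts over splits were as follows. Where more than 100 splits were possible, the real one and others drawn at random made up 100. Pachón against surface fish in controls gave 5401 genes, and 1 of 100 splits, the real one, gave as many (at most 1218 in the others), so chance can be excluded at the 5% level. In starved fish 1 of 90 splits, the real one, gave as many as 5617 (at most 1977 in the others), so chance can be excluded at that level there as well. Old against new batch gave 194 genes, and 3 of 100 splits gave as many (at most 233 in the others). The split with 233 shared 7 of its 8 old-batch libraries with the real one. The share of such splits was under the 5% level without adjustment for the other comparisons, so chance is excluded only at that unadjusted level. For the difference of the response between morphs chance cannot be excluded, since 39 of 100 splits gave as many as the 4 genes found. The most was 664, in a split that mixed the Pachón labels. That split kept the real surface labels, and with them the surface response. The splits exchanged labels in both morphs, so others may keep part of that response. Their share is therefore no test of whether the responses of the morphs were equal. For starvation in Pachón over both batches edgeR found 0 genes (1142 at an unadjusted p under 0.05, 12 by DESeq2) and at most 4 in the other splits; each of the 100 splits gives at least 0, so this comparison says nothing about chance. In the old Pachón batch 14 of 35 splits gave as many as the 1 gene found, with at most 11, so chance cannot be excluded.

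Differences between groups by their own test were found for the following. The Pachón response minus the surface response was 2.08 for TINAGL1, 1.44 for thbs3b, 2.63 for itga3b and 3.72 for ENSAMXG00000001295, the 4 genes called, and camera called 11 lists. Without single libraries that count of 4 genes was 22 (surface old control 2), 15 (surface old starved 2), 13 (surface new control 1), 1 (Pachón new control 1), 818 (surface new starved 1) and 2 (Pachón new starved 1). The surface response differed between batches for 55 genes and 5 lists, among them endothelium (median 1.5 in old minus new). The Pachón response differed between batches for 12 lists, among them ribosomal proteins (median -0.33) and hepatocytes (2.05), and for 0 genes by edgeR (481 at an unadjusted p under 0.05, 1 by DESeq2). The batch effect differed between morphs for 159 genes and 7 lists. With an estimated correlation, 0 of these lists were called.

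Single samples stood apart from the other 3 of their group by Dixon's criterion in 37 of the 480 groups of 4 tested. For normally distributed values 24 would be expected. A gene without a count in 3 libraries is flagged by any read in the other, as for hlfb, sting1 and ubtd1a. The excess over 24 can therefore not be read as more samples standing apart than by chance. Among list scores this was -0.358 for the egg coat in surface old control 3, 0.214 for granulosa cells in Pachón old control 1 and -0.138 for steroid synthesis in Pachón old starved 2. The rest were CPM values of single genes. In surface old controls they were 8.53 for ADAMTSL2, 0.152 for rag1 and 0.152 for ucp1 (replicate 2), 18 for ahsg2, 10.4 for arxa, 4.77 for lhx9 and 21.1 for or70a15 (replicate 4), 1.22 for alox12, 0.174 for hlfb and 0.174 for sting1 (replicate 1), and 1.91 for hsd3b2 and 2.29 for inhbaa (replicate 3). In Pachón old controls they were 6.49 for chrna4b, 135 for per3 and 6.99 for slc26a4 (replicate 2), and 0.178 for both LRRC73 and plpp7a (replicate 3). In Pachón old starved fish replicate 3 had 3090 for ccnb2, 2.36 for COL14A1, 369 for rpl11, 1180 for zar1, 13.1 for fbp1a and 44.1 for rad51c. Replicate 4 had 0.262 for CPA6, 29.3 for dmrta2, 6.93 for figla, 0.131 for LRRC73, 0.262 for ptprja and 0.131 for ubtd1a. Replicate 1 had 39.2 for col1a1b, 0.171 for plpp7a and 31 for uqcrq, and replicate 2 had 0 for rag1 and 73.7 for thbs3b.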

How the results depend on the processing

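The crossed replicate block and the permutation of list scores were chosen after the data were seen; all other alternatives were set before. Counts of genes called in the fit described in the report were 23 and 652 for starvation in surface fish of the old and new batch, 1216 over both, 1, 0 and 0 for the same in Pachón, 4 for the difference between morphs, 55 and 0 for the difference between batches in surface fish and Pachón, 5401 and 5617 for Pachón against surface fish in control and starved fish, and 194 for old against new batch. RLE normalization and leaving out abundant genes kept every count within 1.5 times, and no filter did so except for the batch difference in Pachón (1). In control fish the morph count stayed within 1.5 times in every alternative.

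DESeq2 called 301 and 1116 for surface fish of the old and new batch, 5 for each Pachón batch, 12 for Pachón over both, 107 for the difference between morphs, 193 and 1 for the difference between batches in surface fish and Pachón, and 486 for old against new. Voom with sample weights called 78, 3 and 0 for surface fish of the old batch, the new batch and both (0 with a smallest adjusted p of 0.0773 and 2178 genes at an unadjusted p under 0.05), 0 for the difference between morphs (824 at an unadjusted p under 0.05), 0 and 1 for the difference between batches in surface fish (651) and Pachón, 3489 for the starved morphs and 489 for old against new. EdgeR on only the groups compared called 0 for surface fish of the old batch (2445 at an unadjusted p under 0.05), the new batch (1390) and both (2919), 0 for the batch difference in surface fish (1015), 2 for each Pachón batch and 298 for old against new. This fit takes the spread from fewer samples, which had a dispersion of 0.0742 in surface and 0.0325 in Pachón libraries; it was not run for the difference between morphs. Limma-trend on scaled CPM called 40 (pseudocount 1) and 98 (0.1) for the old surface batch, 1 (0.1) for the new Pachón batch and 1 (pseudocount 1) for Pachón over both. The effect shared across batches left 1 gene for the difference between morphs. Apart from the dispersions, the cause was not tested.

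No pairing by replicate number was seen, though it is not excluded. In the old batch, deviations from group means correlated on average by 0.00382 between libraries with the same number (18 pairs, -0.175 to 0.113). With other numbers the mean was -0.00128 (54 pairs). In the new batch the mean was -0.0683 with the same number and 0.0683 with other numbers (12 pairs each). Groups there hold 2 libraries, whose deviations mirror each other, so these pairs say little about pairing. The replicate block gave 3 and 311 genes for surface fish of the old and new batch, 493 over both, 26 for the batch difference in surface fish and 20 for old against new, and it left every other count within 1.5 times. With crossed numbers in the starved new batch (correlation of -0.195 as numbered) the block called 603 genes in the new batch and 1126 over both. Among 178 gene changes and 50 list calls followed through the alternatives, it ended 41 and 7 calls.

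With an estimated correlation camera called 0 lists for surface fish (16 with the preset one), 0 for Pachón (12), 0 for the difference between morphs (11), 0 for control (3) and 0 for starved morphs (1), and 1 for the batches (7). Fry called 18, 0, 2, 14, 14 and 1 in that order. In the permutation of list scores within batches the smallest adjusted p was 0.108 in surface fish and 0.186 in Pachón, with 13 and 3 lists at an unadjusted exact p under 0.05.

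Leaving out each library in turn gave counts of 13 to 375 for surface fish of the old batch, 196 (without surface new starved 2) to 3661 (without surface new starved 1) for the new batch, and 427 to 4360 for both, at the same 2 libraries. The ranges were 1 to 3 and 0 to 1 for the Pachón batches, 0 to 3 for both, 1 to 818 for the difference between morphs, 24 to 526 and 0 to 1 for the batch differences, and 60 to 409 for old against new. They were 4063 to 6207 and 4330 to 6207 for the control and starved morphs. In Pachón the values of genes near 0 changed sign: cyp19a1a lay between -0.18 and 0.61, gdf9 between -0.0116 and 0.0404 and bmp15 between -0.0462 and 0.145. The oocyte list in the difference between morphs lay between -0.34 and 0.03. No other named gene or list changed direction in any alternative run for it. All named calls for starvation in surface fish were lost with sample weights and in the surface libraries alone. On simulated data for the surface response 40% of genes changed 1.5-fold and 96% of those changed 8-fold were recovered. Those data had the spread of the fit of all libraries, not the larger spread of the surface libraries.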

Other observations

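The comparisons of read shares were chosen after those shares had been seen, and the lists described here were picked from the fixed ones after their results were seen.

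Single members of 6 further lists, none of them called by camera, differed between Pachón and surface controls. Of 74 mitochondrial ribosome genes 25 were higher and 7 lower in Pachón (26 and 9 adjusted over the list alone), with mrpl42 at 1.2 ± 0.14 (edgeR adjusted p = 2.68e-06). Of 48 DNA repair genes 11 were higher and 3 lower (9 and 1 adjusted over the list alone), among them the recombination gene rad51c at 0.88 ± 0.15 (edgeR adjusted p = 0.000167). Glycolysis and gluconeogenesis genes went both ways, with 9 higher and 6 lower of 23 (10 and 7 adjusted over the list alone), the pyruvate kinase gene pklr at 2.27 ± 0.27 and the fructose bisphosphatase gene fbp1a at -1.28 ± 0.15 (edgeR adjusted p = 4.02e-06 and 2.92e-06). In the list of p53 and apoptosis genes 4 of 24 were higher and 9 lower (5 and 9 adjusted over the list alone). Of 24 genes linked to insulin, IGF and FOXO, 8 were higher and 3 lower (8 and 3 adjusted over the list alone), with the cyclin gene ccng2, a FOXO target, at 3.30 ± 0.33 (edgeR adjusted p = 4.78e-07). In the oxidative stress list 7 of 32 were higher and 9 lower (8 and 9 adjusted over the list alone), with txnrd3, a thioredoxin reductase gene on 2 gene rows, at -2.06 ± 0.12 and the ferritin gene fth1b at 1.66 ± 0.14 (edgeR adjusted p = 3.95e-10 and 4.02e-08). The calls of the genes named held in every alternative that was run.

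In starved surface fish the amino acid transporter gene slc38a2 changed by -2.21 ± 0.46 and xbp1, a regulator of the unfolded protein response, by -1.80 ± 0.39 (edgeR adjusted p = 0.00842 and 0.0109). The first call was lost without surface new starved 2 (adjusted p = 0.061), the second without surface old starved 1 (0.0555), and both with sample weights and in the surface libraries alone. The meiosis gene hormad1 rose by 1.06 ± 0.24 (edgeR adjusted p = 0.0128), a call lost without surface old starved 1 (0.0946), surface new control 2 (0.0703) or surface new starved 2 (0.0569) and in the same 2 alternatives. It was also higher in Pachón than in surface controls, by 1.95 ± 0.23 (edgeR adjusted p = 2.43e-06).

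The share of unmapped reads was lower in starved libraries of both morphs, by -1.04 percentage points in surface fish (exact permutation p = 0.0222, adjusted p = 0.0355 over 8 tests) and by -1.7 in Pachón (exact permutation p = 0.00476, adjusted p = 0.0222). Starved Pachón libraries held more counts in genes than controls, a mean of 6.68 ± 0.713 against 5.37 ± 0.334 in units of 1e+06 counts (SD, n = 6 each, exact permutation p = 0.00952, adjusted p = 0.0222), and in surface fish the means of 6.35 ± 0.651 and 5.81 ± 0.476 (SD, n = 4 and 6) did not differ beyond the spread (exact permutation p = 0.156).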
